A study of Rattus norvegicus with 6 samples.

How the data were processed

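Small RNA was sequenced from extracellular vesicles released by rat dedifferentiated fat (DFAT) cells, with 3 vesicle samples from cells not yet induced (0 d) and 3 from cells kept for 14 d in osteogenic induction medium. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a small RNA library kit. The submitters' processing notes name cutadapt 1.9.3, Novoalign 3.02.12 and the rat build rn6, without saying what each was used for. The tool that counted the tags, the version of the miRNA annotation and the tool that predicted unannotated miRNAs are not given in the sources used here.

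Per the file headers, the deposited raw table holds tag counts per mature miRNA for each of the 6 libraries. It has 483 lines with 453 names and 417 different mature sequences, because a mature miRNA made from several precursors, or a predicted sequence with several names, is repeated with the same count. The smallest listed count was 2 in each library, and a blank was taken as 0. A second deposited table holds a normalized score, which per the file headers is a normalized tag count. When it was compared with the raw counts, each library's values equalled the raw count times 1 factor per library, to within 1 count plus 0.5%, for 95.5% to 100% of the values. The factors were 1.39, 1.32 and 1.29 in the 0 d libraries and 4.40, 2.25 and 3.62 in the 14 d libraries. How the authors chose them is not given in the sources used here.

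The 14 d and 0 d groups were compared with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, 2-sided, with trimmed mean of M-values (TMM) factors, with the group as the only term and with Benjamini-Hochberg adjustment. A call required an adjusted p below 0.05. Lines with the same mature sequence were merged into 1, a choice made after the repeated lines had been seen. Low counts were removed with edgeR's default filter (minimum count 10, minimum total 15), which kept 119 sequences holding 99.1% to 99.7% of each library's counts. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Fold changes of sequences with no count in 1 group are given as bounds against a floor of 3 counts in each library of that group. Sequences with 1 to 3 counts in a group are given as a ratio of group totals with a 95% interval from the exact binomial (Clopper-Pearson) method. Such bounds and intervals cover counting error only.

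The tests, 17 miRNA lists, the naming rule and the alternatives were fixed before the data were examined. The lists are the let-7, miR-29, miR-30 and miR-34 families, the miR-17~92 cluster with its paralogs, the Dlk1-Dio3 locus, miRNAs known to promote or inhibit osteogenesis or adipogenesis, and miRNAs abundant in mesenchymal, leukocyte, erythrocyte and serum, endothelial, muscle, epithelial or neural sources. The 11 lists with at least 3 tested members were tested with camera (limma 3.58.1, 2-sided, preset correlation 0.01), with camera under an estimated correlation and with fry, adjusted over these lists. The camera test asks whether a list moves differently from the other miRNAs, and fry asks whether its members move on balance in 1 direction. Named miRNAs are the 8 largest changes in each direction among calls with a mean abundance of at least 50 CPM (TMM-scaled) and groups that do not overlap, the 10 most abundant miRNAs, and, in each list, up to 3 abundant members and up to 2 with the smallest p. Other list members and pairs are named where a count needed them, after their values had been seen. Shares of counts and the number of miRNAs detected were compared with exact 2-sided permutation tests. With 3 samples against 3, the smallest p of those tests is 0.1.

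Total counts ranged from 58730 to 164424 per library. On data simulated from the means and depths of these 119 sequences (20 runs), the test called 10.7% of 2-fold, 36.8% of 4-fold, 70.3% of 8-fold and 94.6% of 32-fold changes in the right direction, and 1.10% of unchanged sequences. Both simulated groups had the same starting profile, and as many sequences rose as fell. These rates therefore do not cover a change in composition between the groups, such as the TMM factors of these libraries show. The common biological coefficient of variation was 0.63. Alternatives were RLE and upper-quartile factors, total counts alone, DESeq2 1.42.0, no filter and a stricter filter, the replicate number as a block, leaving out each library, limma on log2 of the authors' normalized score with a pseudocount of 1 or 0.1, and other thresholds. Chosen after seeing the data were 1 line per name, annotated miRNAs only, libraries thinned to 58730 counts, and total counts without miR-21-5p. Predicted sequences without a miRNA name are given by their sequence. The gene table used for neighbouring precursors is of assembly GRCr8, which is not the build of the deposited files, so no coordinates are given.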

Results

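DFAT cells are fibroblast-like, multipotent cells obtained from mature fat cells by ceiling culture, in which floating adipocytes attach and lose their lipid. The small RNA of extracellular vesicles from rat DFAT cells was counted before induction (0 d, n = 3) and after 14 d in osteogenic medium (n = 3), which addresses how osteogenic conditioning changes the miRNA cargo of the vesicles. The 0 d libraries held 152275, 164424 and 120766 miRNA counts and the 14 d libraries 61121, 73236 and 58730. The means were 145820 ± 22530 and 64362 ± 7777 (SD, n = 3 each; exact permutation p = 0.1, the smallest this design allows). Replicates of a group differed by more than sampling noise in each pair, with Pearson correlations of log2 CPM across miRNAs of 0.881 to 0.956. The labels do not say that the samples came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

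The vesicle cargo was dominated by miR-21-5p, a miRNA abundant in stromal cells, which held 36.7% ± 6.65 of the counts at 0 d and 63.6% ± 4.62 at 14 d (SD, n = 3 each). The let-7 family, known for restraining growth and stem cell genes, held 31.8% ± 2.80 at 0 d and 5.54% ± 2.94 at 14 d. Within it, let-7c-5p went from 12.0% ± 1.07 to 1.14% ± 0.734 and let-7b-5p from 10.2% ± 0.179 to 0.894% ± 0.542. The liver-derived miR-122-5p, common in serum, held 5.51% ± 4.49 and 0.523% ± 0.0999, with a 0 d mean of 2.93% without 0 d replicate 3. The 10 most abundant miRNAs of each library together held 80.5% ± 1.16 at 0 d and 87.6% ± 1.54 at 14 d. For the shares of miR-21-5p, the let-7 family and the 10 most abundant miRNAs the exact permutation p was 0.1, the smallest possible. After thinning to 58730 counts, 195 ± 36.9 sequences were detected at 0 d and 175 ± 16 at 14 d (exact permutation p = 0.5), a difference within the spread between replicates.

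**Figure D1:**
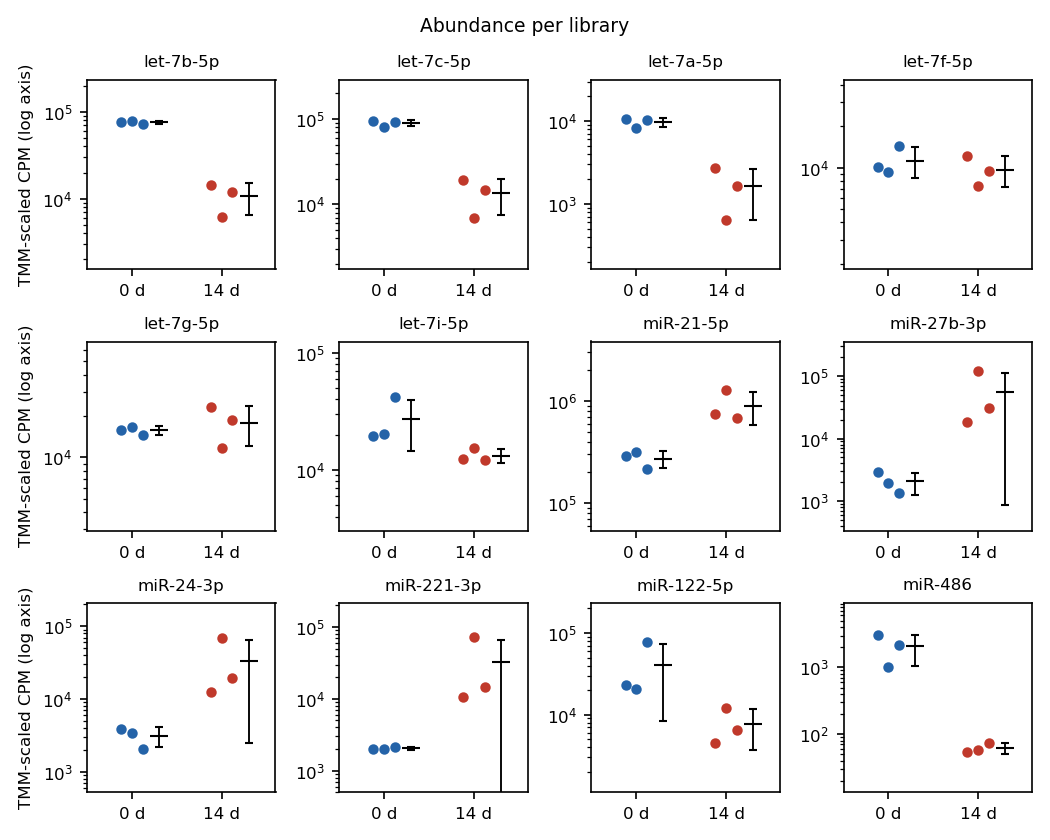
TMM-scaled CPM (log axis) of 12 miRNAs in each vesicle library at 0 d (blue) and 14 d (red); points are libraries, black dashes and bars the mean and SD (n = 3), and a bar runs off the axis where the SD exceeds the mean. The let-7b-5p and let-7c-5p libraries of the 2 groups do not overlap, whereas those of let-7f-5p and let-7g-5p do.

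Of 119 sequences tested, 65 differed between 14 d and 0 d vesicles, 31 higher and 34 lower at 14 d, and for each of the 65 the 3 libraries of one group lay outside the range of the other. Over all tested sequences, 93 (78.2%) had groups that did not overlap, against 10% by chance. Annotated miRNAs made up 23 of the higher and 29 of the lower calls, and 27 higher and 25 lower calls were at least 4-fold, with sequences not listed in 1 group taken at their bounds. Among the annotated miRNAs of the 10 most abundant sequences, miR-27b-3p, an inhibitor of adipogenesis, had the largest rise, at a log2 fold change of 4.78 ± 0.84 (SE, n = 3 per group; edgeR adjusted p = 0.00355). miR-152-3p rose by 2.93 ± 0.69 (adjusted p = 0.0102) and miR-21-5p by 1.73 ± 0.45 (adjusted p = 0.0142), while let-7b-5p fell by 2.82 ± 0.44 (adjusted p = 0.00277) and let-7c-5p fell by 2.71 ± 0.47 (adjusted p = 0.00355). Without 14 d replicate 2, whose TMM factor was 0.47 against 0.92 in both other 14 d libraries, miR-27b-3p was at 3.60 and miR-152-3p at 1.97, both still called.

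The balance of directions depended on the setting. Total-count scaling shifted the log2 fold changes of the tested sequences by a median of -0.87 and gave 18 higher and 46 lower calls, that is 28.1% higher against 47.7% with TMM. The authors' normalized table, tested with limma, which changes the test as well as the scaling, shifted them by a median of -0.75 and gave 20 higher and 44 lower (31.2% higher; 17 and 36 with a pseudocount of 0.1, 23 and 44 without a filter). Thinned libraries changed the depth, had their TMM factors estimated anew and left 105 sequences tested. They shifted the log2 fold changes by a median of 0.79 and gave 42 higher and 23 lower (64.6% higher). Upper-quartile factors shifted them by a median of -0.29, with 31 higher and 40 lower. The miR-21-5p call ended with total counts (log2 0.79, adjusted p = 0.0532), with the authors' table (0.94, adjusted p = 0.257) and with no filter (1.48, adjusted p = 0.204). None of the 65 calls changed sign in any setting that tested it. Fold changes from the authors' table and from TMM had the same sign for 111 of 119 sequences (Pearson correlation across sequences 0.971, Spearman 0.984; sequences are not independent replicates).

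**Figure D2:**
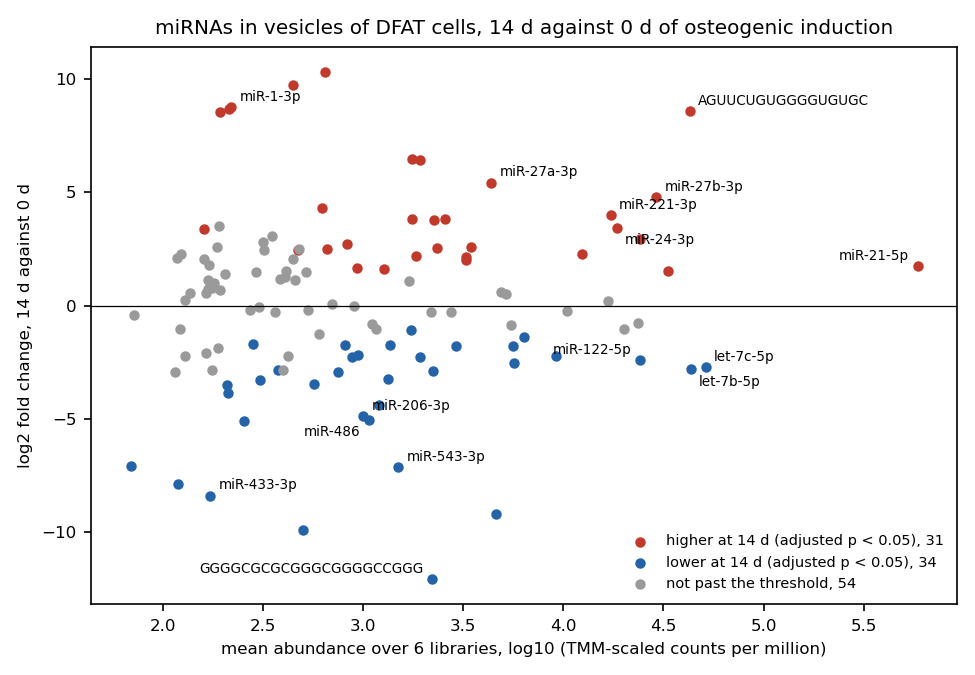
Fitted log2 fold change (14 d against 0 d) of the 119 tested sequences against mean abundance over the 6 libraries (log10 of TMM-scaled CPM), each point a sequence, red or blue where the adjusted p passed 0.05 (31 higher, 34 lower). Fitted values of sequences with no count in 1 group, such as miR-1-3p and miR-433-3p, depend on the prior count, and total-count scaling shifted the fold changes by a median of -0.87.

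All 9 members of the let-7 family were tested, and 6 fell while none rose. Besides let-7b-5p and let-7c-5p these were let-7a-5p (fell by 2.55 on the log2 scale), let-7d-5p (fell by 1.78), let-7e-5p (fell by 2.26) and miR-98-5p (fell by 2.87). For let-7i-5p, let-7f-5p and let-7g-5p the values were -1.04, -0.22 and 0.19, not past the threshold, and let-7i-5p was called lower with total counts (-1.91, adjusted p = 0.00741). It was also called lower with upper-quartile factors (-1.32, adjusted p = 0.0367), the authors' table with a pseudocount of 1 (-1.70, adjusted p = 0.0227) and 1 line per name (-1.79, adjusted p = 0.018). The lower count was 6 adjusted over the list alone, and 5 to 7 under RLE, upper-quartile, total-count and the authors' scaling, with none higher. The family's camera adjusted p was 0.05004, just short of the threshold (0.666 with an estimated correlation), while fry gave an adjusted p of 0.0129. The let-7d-5p call was lost without any 1 of 4 libraries (0 d replicate 1, -1.69; 0 d replicate 2, -1.58; 0 d replicate 3, -1.82; 14 d replicate 3, -1.71), was -2.46 without 14 d replicate 1, and the let-7e-5p call was lost without 14 d replicate 3 (-2.27), which left 4 members lower. Thinning ended the calls of let-7a-5p (-1.55), let-7d-5p (-0.71) and let-7e-5p (-1.30), which left 3 members lower. The let-7d-5p call was also lost with RLE factors (-1.72) and with the authors' table (-2.87).

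Of 13 tested miRNAs of the imprinted Dlk1-Dio3 locus, 8 fell and none rose, also when adjusted over the list alone and, with 8 to 11 lower, under the other scalings named above. The lower count was 5 without 14 d replicate 3, with miR-434-3p, miR-379-5p (fell by 3.29; adjusted p = 0.132 without that library) and miR-493-5p no longer called. Without 14 d replicate 1, 1 of 18 members then tested was higher, miR-300-3p, which had too few counts to be tested over all libraries. The miR-493-5p call (fell by 1.69, adjusted p = 0.0493) was lost without any 1 library other than 0 d replicate 3 (-1.45 to -1.84) and after thinning (-0.92), which left 7 members lower, and miR-379-5p was at -4.84 without 14 d replicate 2 and -2.63 without 14 d replicate 1. The list passed camera (adjusted p = 0.012; median log2 fold change -2.94, or -2.23 with uncounted members at their bounds), and the call was lost with an estimated correlation (adjusted p = 0.605). Its share of counts was 1.37% ± 0.341 at 0 d and 0.133% ± 0.0268 at 14 d (SD, n = 3 each; exact permutation p = 0.1). miR-543-3p had 1693 counts over the 0 d libraries and 3 over the 14 d libraries, a ratio of 138 (95% interval 47.2 to 670; adjusted p = 0.0015), and miR-127-3p had 297 and 2, a ratio of 36.3 (9.97 to 301; adjusted p = 0.00671). miR-433-3p was not listed at 14 d and was at least 5.2-fold lower (adjusted p = 0.00652), and miR-434-3p was at least 2.1-fold lower (adjusted p = 0.0192, but 0.0638 without 14 d replicate 3). miR-382-5p fell by 3.45 ± 0.81 (adjusted p = 0.0102; -4.80 without 14 d replicate 2) and miR-369-3p fell by 2.21 ± 0.46 (adjusted p = 0.00647). The fitted values of miR-543-3p and miR-127-3p, -7.13 and -5.12, rested on 14 d replicate 1, the 14 d library with their counts (-11.66 and -9.08 without it), and were -6.51 and -4.51 without 14 d replicate 3. The erythrocyte and serum list, like the let-7 and Dlk1-Dio3 lists, held a larger share of counts at 0 d. It held 8.32% ± 4.30 (5.86% without 0 d replicate 3) against 1.04% ± 0.102 at 14 d (SD, n = 3 each, exact permutation p = 0.1). The miR-17~92, leukocyte, endothelial, muscle, epithelial and neural lists also held larger shares at 0 d (exact permutation p = 0.1 each). Shares are relative to the total, of which miR-21-5p held more at 14 d.

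Among miRNAs known to promote osteoblast differentiation, 3 of 9 tested members rose and none fell. They were miR-21-5p, miR-20a-5p of the proliferation-linked miR-17~92 cluster (2.60 ± 0.61, adjusted p = 0.0102) and miR-129-5p (2.70, adjusted p = 0.0303). For miR-26a-5p the log2 fold change was -0.75 and for miR-22-3p it was 0.58, neither past the threshold, but miR-26a-5p passed as lower with total counts (-1.50, adjusted p = 0.0277) and miR-22-3p as higher after thinning (1.38, adjusted p = 0.029), where 6 of 8 tested members rose. Total-count scaling left 1 member higher and 1 lower, since it ended the calls of miR-21-5p and miR-129-5p (1.51). Without 14 d replicate 2 the value was 1.72 for miR-20a-5p and 1.38 for miR-129-5p, which was then not called, and neither was it without 0 d replicate 3 (2.39). The list did not pass camera (adjusted p = 0.285, median 1.46).

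Among miRNAs known to inhibit osteoblast differentiation, 7 of 15 tested members rose and 2 fell (camera adjusted p = 0.288, median 2.15). The risen ones included miR-221-3p (3.99 ± 0.80, adjusted p = 0.00628), miR-24-3p (3.43 ± 0.73, adjusted p = 0.0067), and miR-214-3p (3.84 ± 0.76, adjusted p = 0.00602), while miR-125b-5p fell by 2.95 ± 0.60 (adjusted p = 0.00647; -3.56 without 14 d replicate 1) and miR-206-3p fell by 4.88 ± 0.78 (adjusted p = 0.00281; -5.48 without that library). Under total-count scaling 3 rose and 3 fell, and after thinning 9 of 14 rose and 2 fell. miR-34c-5p, a p53 target of the miR-34 family, rose by 2.20 ± 0.71 (adjusted p = 0.0319), but was not called with total counts (1.06) or without 14 d replicate 2 (1.13), 0 d replicate 1 (1.89) or 0 d replicate 3 (2.15). Without 14 d replicate 2 the values of miR-221-3p, miR-24-3p and miR-214-3p were 2.64, 2.35 and 3.10, all still called, whereas miR-34c-5p, miR-23a-3p (1.39) and miR-145-5p (4.41) were not, so that 4 rather than 7 members rose. miR-23a-3p (adjusted p = 0.0444 over all libraries) lost its call without any 1 library other than 14 d replicate 1 (1.39 to 2.24). Its call was also lost with total counts (0.97) and with the authors' table (1.40). The counts for both osteogenesis lists were the same adjusted over the list alone.

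In the miR-30 family, which targets Runx2, 2 of 3 tested members rose (camera adjusted p = 0.288; the same 2 adjusted over the list alone). They were miR-30a-5p (3.77 ± 0.70, adjusted p = 0.00499) and miR-30d-5p (2.28 ± 0.66, adjusted p = 0.0226), and without 14 d replicate 2 they were at 2.75 and 1.55. miR-30d-5p was not called with total counts (1.22, adjusted p = 0.0792). For miR-30c-5p the value was -0.09. In the miR-29 family, which targets collagens, the 1 tested member, miR-29a-3p, was at 1.11 and not past the threshold.

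Among miRNAs known to inhibit adipocyte differentiation, 4 of 6 tested members rose and 1 fell (camera adjusted p = 0.288, median 4.15), and the list's share of counts was 1.07% ± 0.210 at 0 d and 5.90% ± 3.68 at 14 d (3.84% without 14 d replicate 2). miR-27a-3p (5.42 ± 1.09, adjusted p = 0.00628), miR-27b-3p, miR-221-3p and miR-145-5p (4.32, adjusted p = 0.0433) rose, and miR-224-5p fell by 2.27 ± 0.43 (adjusted p = 0.00521). Without 14 d replicate 2, miR-27a-3p was at 3.66, miR-27b-3p at 3.60 and miR-221-3p at 2.64. miR-145-5p was counted in 1 of the 3 libraries at 0 d, and its call was lost with total counts (3.55, adjusted p = 0.0532) and without any 1 library other than 0 d replicate 2 (values of 3.54 to 4.48), so that under total counts 3 members rose. Without 0 d replicate 2, the 0 d library with its counts, the fitted value was larger by 5.68. Among miRNAs known to promote adipocyte differentiation, 4 of 10 tested members rose and 2 fell (camera adjusted p = 0.288, median 1.94), against 2 and 2 with total counts 1 and 2 with the authors' table, and 5 and 0 of 8 after thinning. miR-21-5p, miR-30a-5p, miR-143-3p and miR-378a-3p rose, and miR-146b-5p fell by 1.78 ± 0.37 (adjusted p = 0.00652) and miR-320-3p fell by 1.41 ± 0.43 (adjusted p = 0.0266). The miR-320-3p call was lost without 0 d replicate 1 (-1.50), 0 d replicate 2 (-1.06) or 14 d replicate 3 (-1.38) and after thinning (-0.55), and the miR-146b-5p call after thinning (-0.94). The miR-143-3p call (2.16) ended with total counts (1.37), and that of miR-378a-3p (3.82) without 0 d replicate 1 (3.58), 14 d replicate 2 (3.28) or 14 d replicate 3 (4.07). Both calls ended with the authors' table (1.53 for miR-143-3p and 4.45 for miR-378a-3p). The counts for both adipogenesis lists were the same adjusted over the list alone.

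Of the miR-17~92 cluster and its paralogs, 4 members were tested, of which miR-20a-5p rose and miR-25-3p fell by 2.21 ± 0.36 (adjusted p = 0.00289), while miR-93-5p was at 2.44 and not past the threshold (camera adjusted p = 0.713). The miR-93-5p value was 1.18 without 14 d replicate 2 (adjusted p = 0.553) and 2.90 after thinning (adjusted p = 0.029), where 3 members rose and 1 fell. Among mesenchymal miRNAs, 5 of 14 rose and 2 fell with TMM, but 2 rose and 3 fell with total counts, and 7 rose and 1 fell after thinning (camera adjusted p = 0.288, median 1.07 with TMM and 0.08 with total counts). The risen ones were miR-21-5p, miR-152-3p, miR-214-3p, miR-143-3p and miR-145-5p, the fallen ones miR-125b-5p and miR-99a-5p (fell by 1.76; not called without 14 d replicate 3, at -1.53, or after thinning, at -0.97). miR-100-5p was at -0.88, not past the threshold, although it passed as lower with total counts (-1.88, adjusted p = 0.00418) and without 14 d replicate 2 (-1.38, adjusted p = 0.0119). It also passed with upper-quartile factors (-1.26, adjusted p = 0.0285) and the authors' table (-1.72, adjusted p = 0.00387). The same held with 1 line per name (-1.72, adjusted p = 0.011) and total counts without miR-21-5p (-1.06, adjusted p = 0.0442). The calls of miR-21-5p, miR-143-3p and miR-145-5p were those lost with total counts.

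Among miRNAs abundant in red cells and serum, 4 of 6 tested members fell and 1 rose (median -2.30). The camera adjusted p was 0.285 (0.666 with an estimated correlation) and the fry adjusted p was 0.0129. miR-486 fell by 5.04 ± 0.64 (adjusted p = 0.0015), miR-122-5p fell by 2.40 ± 0.67 (adjusted p = 0.0191), miR-25-3p fell as given above and miR-144-5p fell by 3.51 (adjusted p = 0.0432). miR-16-5p rose by 2.50 (adjusted p = 0.0259), a call lost with total counts (1.36) and the authors' table (1.35), and miR-423-5p was at -0.30. The miR-122-5p value was -1.52 without 0 d replicate 3, and its call was lost without 14 d replicate 3 (-2.28). Calls were lost for miR-144-5p without 0 d replicate 1 (-3.22), 14 d replicate 1 (-2.91) or 14 d replicate 2 (-3.04) and after thinning (-2.56), which left 3 members lower. The miR-16-5p call was lost without 0 d replicate 3 (2.41) or 14 d replicate 2 (1.42). Without 14 d replicate 3, the 14 d library with its counts, miR-144-5p was fitted at -8.72.

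Of 3 tested muscle miRNAs, 1 rose and 1 fell (camera adjusted p = 0.916). miR-1-3p was not listed at 0 d and was at least 28.3-fold higher at 14 d (adjusted p = 0.00289), whereas miR-206-3p, which shares its seed, fell, and miR-499-5p was at 0.56, not past the threshold (-0.46 with total counts, which turned the list's median negative). Lists with fewer than 3 tested members had no set test. The endothelial miR-126a-3p fell by 1.76 ± 0.46 (adjusted p = 0.0142; not called without 14 d replicate 1, at -1.57, or 14 d replicate 3, at -1.82, or after thinning, at -0.87). The neural miR-128-3p fell by 1.09 ± 0.37 (adjusted p = 0.0376), a call lost without any 1 library other than 14 d replicate 2, with values of -0.94 to -1.17, with RLE factors (adjusted p = 0.0506) and after thinning (-0.15, adjusted p = 0.807). The neural miR-7a-5p was at 2.03 (1.45 to 3.20 with 1 library left out), past the threshold only after thinning (2.64, adjusted p = 0.0307) among the settings run. The leukocyte miR-146a-5p was at -2.83 (adjusted p = 0.0719; 1 lower adjusted over the list alone) and the epithelial miR-192-5p at -1.27, neither past the threshold. Both passed as lower with total counts, with upper-quartile factors and with the authors' table (miR-146a-5p not with a pseudocount of 0.1). With 1 library left out, miR-146a-5p passed without 0 d replicate 1 (-3.23, adjusted p = 0.0359) and miR-192-5p without 14 d replicate 2 (-1.95, adjusted p = 0.0263). Over such fits miR-146a-5p, tested in 4 of 6, ranged from -3.54 to -2.21 and miR-192-5p from -1.95 to -0.90. For all other lists the counts adjusted over the list alone were those over all sequences.

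**Figure D3:**
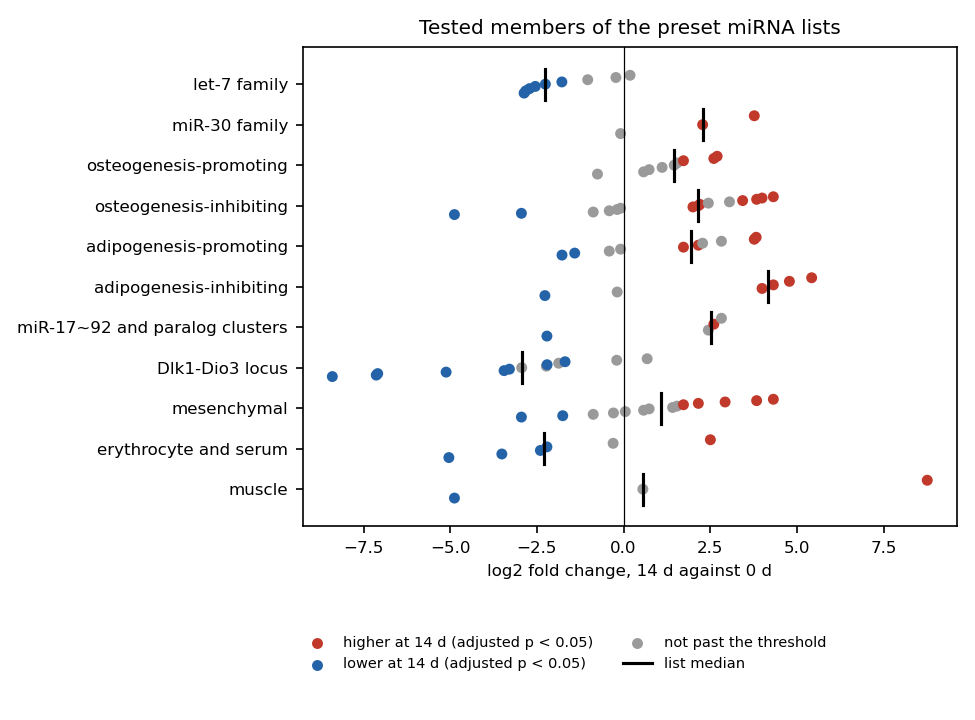
Log2 fold change (14 d against 0 d, TMM scaling) of the tested members of the 11 miRNA lists with at least 3 tested members, each point a miRNA, red or blue where the adjusted p passed 0.05 and grey otherwise, black lines marking list medians. The let-7 (median -2.26) and Dlk1-Dio3 (median -2.94) lists have no risen member, and the muscle median (0.56) turned negative with total counts.

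Of 15 tested predicted sequences without a miRNA name, 8 rose and 5 fell, and all predicted sequences together held 5.07% ± 0.923 of counts at 0 d and 10.2% ± 2.60 at 14 d (SD, n = 3 each; exact permutation p = 0.1). That difference was carried by 1 of them, AGUUCUGUGGGGUGUGC, at 0.0307% ± 0.0373 and 5.57% ± 2.34, and without it the shares were 5.04% ± 0.923 and 4.62% ± 0.550 (exact permutation p = 0.7). The 17-nt AGUUCUGUGGGGUGUGC had 13, 16 and 89 counts at 0 d and 1753, 5197 and 3955 at 14 d, a log2 fold change of 8.58 ± 1.25 (adjusted p = 0.00204; 10.25 without 0 d replicate 3 and 7.87 without 14 d replicate 2). AGGGCUGGAGAGAUGGC rose by 6.48 ± 0.85 (7.10 without 0 d replicate 2, 5.75 without 14 d replicate 2) and GGGGCUGGAGAGAUGGC by 6.42 ± 0.75 (5.69 without 14 d replicate 2). Sequences not listed at 0 d were AGGGAGGCUCUGGAGGC, at least 83.5-fold higher at 14 d, AAGGAUGGCUGAUUUUAGC, at least 57.8-fold, AGACUGAGCACGAGAGGC, at least 27.5-fold, and AGGAAGCUGUUCUGAGGG, at least 25.0-fold. These bounds were 37.7, 18.9, 11.2 and 15.9 without 14 d replicate 2. ACAGUAGUCUGCACAUUGGUU rose by 1.52 ± 0.39 (adjusted p = 0.0141), a call lost with total counts (0.63) and without 0 d replicate 1 (1.44). The call was also lost with the authors' table (0.78, adjusted p = 0.228), no filter (1.30, adjusted p = 0.15) and 1 line per name (0.89, adjusted p = 0.0658). This sequence is miR-199a-3p without its last base and was more abundant than the full form (mean log2 ratio 2.81 at 0 d and 4.74 at 14 d). It is not counted in the mesenchymal list, which holds the full form. Of those that fell, GGGGCGCGCGGGCGGGGCCGGG was at least 67.1-fold lower, AUCUCGCUGGGGCCUCC at least 15.2-fold (9.7 without 0 d replicate 3) and CGCGGGCGGGGCCGGGGG at least 3.6-fold. AUCUCGGUGGGACCUCCA had 5189 counts over the 0 d libraries and 2 over the 14 d libraries, both in 14 d replicate 2, a ratio of 635 (95% interval 176 to 5240).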

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

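The alternatives using 1 line per name, annotated miRNAs only, thinned libraries or total counts without miR-21-5p were chosen after the data were seen. Total calls stayed between 50 and 83 under every change of scaling, filter, tool or library and fell to 34 (15 higher, 19 lower) at an adjusted p below 0.01. The higher count left a range of 1.5 times the main one with total counts (18), DESeq2 (47) and limma on the normalized table (20, or 17 with a pseudocount of 0.1). DESeq2 was run without edgeR's filter, so its 83 calls were among 214 tested sequences. It kept 30 of the 31 higher and 32 of the 34 lower main calls. Leaving out each library gave 50 to 69 calls, 23 to 39 higher and 24 to 34 lower. With 1 line per name there were 82 calls (38 higher, 44 lower) among 133 tested lines, where a sequence with several names counts more than once. This setting kept 25 of the 31 higher and all 34 lower main calls. The cause of each difference was not tested, except that a stricter threshold allows fewer calls by construction. The 0 d totals were above the 14 d ones, and changes of 2-fold were mostly out of reach (10.7% called in simulated data).

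The let-7 list, at 0.05004, passed with no filter (0.000521), limma without a filter (0.00058), fry (0.0129), annotated miRNAs only (0.0386) and the replicate block (0.0372), and ranged from 0.00664 to 0.0852 when a library was left out. With an estimated correlation its adjusted p was 0.666. The Dlk1-Dio3 call ended only with an estimated correlation among the alternatives run (0.605). With no filter the miR-30, mesenchymal, and erythrocyte and serum lists passed (0.0441 each), the last also with limma without a filter (0.0388) and fry (0.0129), but at an adjusted p of 0.666 for each of the 3 with an estimated correlation. The muscle list, never past the threshold, changed direction with upper-quartile factors (0.978), the replicate block (0.934), 1 line per name (0.851) and total counts without miR-21-5p (0.974), and in 3 of the 6 fits with a library left out (0.753 to 0.959 over the 6).

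Reversed single miRNAs had not been called. miR-22-3p was at -0.29 with total counts, -0.17 with each limma setting and -0.063 with 1 line per name. miR-499-5p was at -0.46, -0.20 and -0.35 in these settings, and -0.12 to 0.97 with a library left out. miR-30c-5p was at 0.033 with the stricter filter, 0.15 with the replicate block, 0.73 thinned and -0.52 to 0.33 with a library left out. Thinned, miR-26a-5p was at 0.14 and miR-423-5p at 0.56. The cause was not tested.

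No clear pairing of the samples by replicate number was seen, although 3 samples per group cannot exclude one. Deviations of same-numbered samples correlated at -0.02, 0.04 and 0.17, and not every sample correlated best with its own number. With the replicate block there were 62 calls (31 higher, 31 lower), which included 28 of the 31 higher and 30 of the 34 lower main calls.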

Other observations

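The pairs, and the tests of scaling, depth by thinning, GC content, serum, short tags, cluster members and arms, were chosen after the data were seen, and the tests of sample splits and the sequence motif before their results were seen. Closely related miRNAs did not always move together, and a ratio within a library does not depend on the scaling. The log2 ratio of miR-221-3p to its cluster partner miR-222-3p was 2.91 ± 0.71 at 0 d and 6.44 ± 1.10 at 14 d (SD, n = 3 each; exact permutation p = 0.1, the smallest possible, here and for the next 3 ratios). That of let-7a-5p to let-7f-5p was -0.19 ± 0.28 and -2.73 ± 0.67. The arms of miR-99b (5p to 3p) were at 4.01 ± 0.49 and 0.11 ± 0.99. The risen ACAGUAGUCUGCACAUUGGUU is miR-199a-3p without its last base, and its log2 ratio to the full miR-199a-3p was 2.81 ± 0.25 at 0 d and 4.74 ± 1.04 at 14 d, while miR-199a-3p itself was at a log2 fold change of -0.29, not past the threshold. Sequences this similar may share reads, so their single values are uncertain.

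A hypothesis that members of a genomic cluster change together gave a median difference in log2 fold change of 2.33 over 39 pairs against 2.75 for random pairs (one-sided permutation p = 0.229), and that arms of a precursor do gave 1.64 over 7 pairs against 2.73 (p = 0.171). Neither passed, and both differences lay on the predicted side, so the hypotheses stay open. The 11 annotated miRNAs with a GGAG or CCCU motif had a mean log2 fold change 0.16 above the other 93 (permutation p = 0.862), which did not pass. No RNA of the cells was analysed here, so this contrast cannot tell loading from expression in the cells. A link with vesicle loading stays open.

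In the let-7 family 6 of 9 tested members fell, and at the Dlk1-Dio3 locus 8 of 13, while miR-27a-3p, miR-27b-3p, miR-24-3p and miR-221-3p rose. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 65 calls and the highest of the others 0; 10 splits are too few for a share under 0.05. The choice of 1 factor per library sets where 0 lies, but it did not move all fold changes by the same amount. From TMM to total counts, let-7d-5p moved by -0.65 and miR-129-5p by -1.19. The fewest calls kept under 3 other scalings were 18 of 31 higher and 32 of 34 lower. Thus 13 of the higher calls depended on the scaling. All of these scalings are relative, so the test cannot decide which sequences rose or fell in amount. Thinning kept 50 of 65 calls, 28 of 31 higher and 22 of 34 lower, and shifted the fold changes by a median of 0.79. More of the lower than of the higher calls were lost, with 3 let-7 and 7 Dlk1-Dio3 members still lower. The TMM factors were estimated anew after thinning, so effects of depth and of a moved 0 cannot be told apart. Fold change did not follow GC content (Spearman rho 0.0138 across sequences). An effect of osteogenic induction stays a hypothesis, because a different culture age, medium or vesicle yield at 14 d was not tested.

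The erythrocyte and serum miRNAs miR-122-5p, miR-486, miR-144-5p and miR-25-3p were higher at 0 d, and a candidate source is serum or blood RNA carried into these preparations. RNA from 1 source keeps its miRNAs in 1 ratio, but miR-122-5p to miR-486 was 7.52, 20.4 and 36.2 in the 0 d libraries, an SD of 1.15 on the log2 scale at the 83.7th percentile of 1653 pairs of miRNAs (median 0.511). That is above the median but not far enough to exclude it, and miR-16-5p of the same list rose. Members with too few counts to be tested were nearly absent from the 0 d libraries. Counts there were 0, 7 and 0 for miR-451-5p, 0, 0 and 0 for miR-144-3p, and 7, 10 and 12 for miR-92a-3p. Of the list, miR-25-3p is also in the miR-17~92 list, and how far DFAT cells themselves express these miRNAs was not tested. No medium without cells was analysed here, so a serum source and release by the cells cannot be told apart.

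Short predicted sequences of 17 to 19 nt rose at 14 d, and tags of at most 19 nt held 1.51% ± 1.08 of counts at 0 d and 6.40% ± 2.70 at 14 d (SD, n = 3 each; exact permutation p = 0.1), but 1.48% ± 1.06 and 0.829% ± 0.371 without AGUUCUGUGGGGUGUGC (exact permutation p = 0.4), which carried that rise. More short inserts at 14 d should raise such tags as a class, and of 10 tested 7 rose and 3 fell. The rule for this test was set after these values had been seen, and several of the tags are nearly alike in sequence. The test therefore cannot decide on short inserts. Repeated genomic copies could contribute, since 2 of the 7 risen tags have several names (15 in all) against 17 of 193 other predicted sequences, but Fisher's exact p was 0.135. Whether these tags are miRNAs at all, or pieces of other RNAs or repeats, was not tested, and no biological explanation was tested.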
